A study of Mus musculus with 9 samples.

How the data were processed

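The 9 libraries were nuclear RNA from whole mouse pancreas, 3 mice per group, prepared with 10000 nuclei loaded per library per the labels. Each library came as a sparse matrix of genes by barcodes. The authors deposited values that are not all whole numbers: per library 1.02% to 10.22% of stored entries were 0, and of the stored entries above 0, 0.35% to 1.16% were whole to within 0.000001. They were therefore taken to be expected counts, in the sense of estimates that need not be whole, and the step that made them fractional is not given in the sources used here. The design had assumed whole raw counts, so the deposited expected counts were summed per library and class and rounded to whole numbers before the count tests. Seurat and Signac, and the builds mm10 and GRCm38, are named per the submitters' processing notes; the aligner is not given in the sources used here. The files held 21337 genes, named by symbol. In 1 to 3 libraries 38 widely detected genes had no entry. Such an entry enters the summed counts, and so the tests, as 0, although it is a missing value; the gene and list tests were therefore run again without these genes, and no single value of theirs is reported as a change.

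Barcodes with at least 500 counts, at least 300 genes and at most 5% mitochondrial counts were kept. The gene minimum removed 1455 of 32329 barcodes, of which 879 were in control replicate 3. Scrublet called 36 doublets, 0.04% to 0.44% of a library, which is too few for a caller that works on libraries of this size, so doublets remain in the data; removal of the 5% highest doublet scores was tried instead. Counts were scaled to 10000 per nucleus and log transformed, 2000 variable genes and 30 principal components were taken without integration across libraries, and nuclei were clustered with 15 neighbours and Leiden resolution 1 (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, Python 3.11.15, matplotlib 3.10.9). This gave 23 clusters, 14 of them acinar-like. The 8182 nuclei outside these were clustered again into 25 clusters, of which 8 stayed unnamed, and 1274 nuclei in all had no name. A cluster took a name when at least 3 markers of a class had a mean at least 2 times the 25th percentile of cluster means and were detected, above 0.5, in at least 10% of its nuclei, unless another class reached 67% of its markers.

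The lists of markers and of genes, the tests, the alternatives first planned and the rule for named genes were fixed before the data were examined. The naming rule for clusters and the second clustering were chosen after seeing the data, and 4 naming rules were tried. A version with detection above 0 left the B cell cluster unnamed, a version with medians gave the same 8 tested classes, and a version against all other nuclei dropped some ductal clusters and was run as an added alternative. Genes could be named when they passed the threshold, did not overlap between the groups, had an average log2 CPM of at least 4, were under 5 times higher in another named class, and had an ordinary symbol, or when they belonged to a fixed list being described. Few genes passed, so the genes named beside each list are list members, called or not.

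Mice were the replicates. For each class the summed counts of the 9 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood test, group as the only term), with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM were computed from the summed deposited counts with TMM scaling. DESeq2 1.42.0 was run as an alternative. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a class and contrast, with an estimated correlation and with fry beside it. Of 101 list tests 31 passed. Of these, 0 passed with an estimated correlation and 0 by fry, which tests whether a list moves one way without comparing it with other genes. The 31 calls thus depend on the preset correlation. Leaving out each library in turn, 15 of the 31 calls held throughout. Median, mean and test differed in sign in 15 list tests, 0 of them called. Shares of nuclei were tested with edgeR on nuclei per class with all kept nuclei as offset, and with exact two-sided permutation tests.

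Summed acinar counts ran from 12356202 to 27530717 per library and the common biological coefficient of variation was 0.302 in acinar-like and 0.219 in beta-like nuclei. Nuclei per library ran from 1390 to 3621 in acinar-like, 148 to 1028 in ductal-like and 52 to 218 in fibroblast-like nuclei. They ran from 37 to 198 in endothelial-like, 25 to 115 in macrophage-like and 11 to 135 in beta-like nuclei, so these classes rest on few nuclei. The test was tried on simulated data drawn from the real means and library sizes with 200 changed genes. For acinar-like nuclei at 7 days, over 12330 genes, 16% of genes changed 2-fold and 61% of genes changed 4-fold were called, with 2 false calls of 79. At 28 days, over 12259 genes, these were 22% and 58%, with 8 false calls of 88. For ductal-like nuclei at 7 days, over 8921 genes, these were 19% and 80%, with 7 false calls of 106. Most simulated 2-fold changes were thus not called at this number of mice, depth and spread, none of which was varied.

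Alternatives were DESeq2, its size factors within edgeR, no filter on low counts, other clustering resolutions, no scrublet removal, all nuclei without classes, nuclei thinned to 1000 counts, the number of sequencing runs as a covariate, fits of the 2 compared groups only, a replicate block, and leaving out each library. Added after seeing the data were leaving out both libraries of 4 runs, leaving out the 5% highest doublet scores, rounding fractional values up, leaving out genes with missing values or rRNA-like genes, markers against all other nuclei, and a minimum of 1000 counts. Coordinates were not used.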

Results

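Single-nucleus RNA sequencing was carried out on whole pancreas of 9 wild-type mice, with nuclei isolated from frozen, powdered tissue. Cerulein, a cholecystokinin analogue that overstimulates acinar cells and induces acute pancreatitis, was injected hourly, 8 times a day on 2 consecutive days. Pancreata were taken from 3 mice 7 days after injection and from 3 mice 28 days after injection. The control group held 3 saline-injected mice, all killed at 28 days, so the 7-day mice were younger at sampling than their controls. The mice were littermates and each group lived in a cage of its own, so cage and group cannot be told apart. The dose per injection was given as 50 mg/kg in one part of the labels and as 50 μg/kg in another, and is therefore uncertain. Each library came from a single mouse, and the comparisons asked how the cells of the pancreas differed from controls during recovery from the injury, early and late.

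The files held 32329 barcodes, of which 30838 were kept as nuclei. Kept nuclei numbered 2806, 3569 and 3714 in controls, 5508, 2890 and 4843 at 7 days, and 3085, 2609 and 1814 at 28 days. Total counts per library ran from 16451280 in control replicate 1 to 31241399 in 7-day replicate 2. Median counts per barcode ran from 3439 in control replicate 3 to 11531 in 28-day replicate 3. The 12 genes that read ribosomal RNA sequence, Gm42418 foremost, took between 46.8% and 69.7% of the counts of a library. Libraries of 7-day replicate 2 and 28-day replicate 3 were pooled from 4 sequencing runs and the others from 6 runs, so no control was in the smaller batch. In 1 to 3 libraries 38 widely detected genes had no entry at all, among them Ptf1a, Reg2, Klk1, Rpl32, Rplp0 and Eef1a1. They enter the sums as 0, none is cited singly as changed, and called lists that hold one are also given without it.

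Nuclei fell into classes that resembled acinar, ductal, fibroblast, macrophage, endothelial, beta, T or NK, and B cells by their marker genes. Acinar-like nuclei, the enzyme-secreting cells, made up 75.1% ± 5.42 of nuclei in controls, 73.7% ± 9.86 at 7 days and 74.2% ± 2.34 at 28 days (SD, n = 3 mice each). Ductal-like nuclei made up 10.3% ± 1.88, 12.8% ± 5.98 and 11.1% ± 3.12 in the same order. Fibroblast-like nuclei stood at 2.37% ± 0.845 in controls, 3.10% ± 0.952 at 7 days and 3.69% ± 0.565 at 28 days, and macrophage-like nuclei at 1.07% ± 0.273, 1.60% ± 0.646 and 1.48% ± 0.208. B cell-like nuclei stood at 1.03% ± 0.595, 0.448% ± 0.298 and 0.509% ± 0.193. Endothelial-like nuclei made up 3.60% ± 0.684, 2.82% ± 1.33 and 3.47% ± 0.664, beta-like nuclei 1.02% ± 0.177, 1.41% ± 1.24 and 1.20% ± 0.293, and T or NK cell-like nuclei 0.532% ± 0.273, 0.461% ± 0.221 and 0.444% ± 0.196. No share differed between groups by edgeR, with the lowest adjusted p at 0.5589 for 7 days and at 0.6551 for 28 days. Fibroblast-like and macrophage-like shares at 28 days lay above every control, which is the smallest p that an exact two-sided permutation test of 3 against 3 mice can give, 0.1. The log2 change of the macrophage-like share was 0.60 at 7 days and 0.47 at 28 days. It went to 0.27 and 0.25 at Leiden resolution 2, and to -0.056 and -0.079 without the removal of scrublet calls. Clustering and naming were redone for both settings. In the main version, cluster 12 of the second clustering stayed unnamed with 16 acinar and 11 macrophage markers. Of its 132 nuclei, 59 came from control replicate 1. Its part in the move without scrublet removal was not tested. Without that removal the exact permutation p at 28 days was 0.3 for fibroblast-like and 1 for macrophage-like shares. Without control replicate 3 the log2 change at 28 days went from 0.64 to 0.37 for fibroblast-like and from 0.47 to 0.27 for macrophage-like shares. Nuclei left without a name made up 3.67% to 7.09% of control libraries, 3.15% to 4.32% of 7-day libraries and 3.21% to 4.29% of 28-day libraries.

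**Figure D1:**
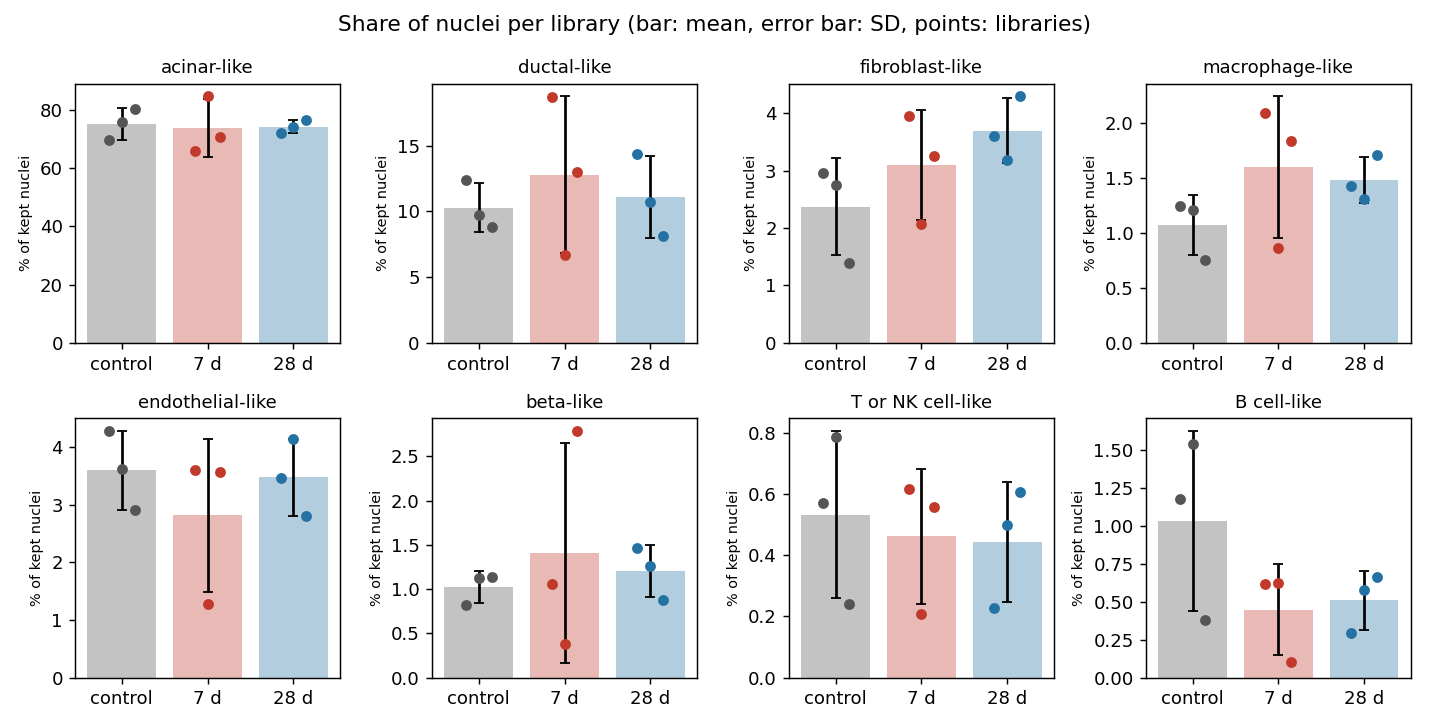
Share of kept nuclei in each named class, one point per library (n = 3 mice per group), with the group mean and SD. The acinar-like share averaged 75.1% in controls, 73.7% at 7 days and 74.2% at 28 days.

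Acinar-like nuclei of the libraries were spread differently over the acinar clusters, which were summed together per library. Cluster 2, led by mitochondrial genes and Cd44, took 1373 of its 1954 nuclei from 7-day replicate 1, and cluster 13, also led by mitochondrial genes, took 942 of 2030 from 7-day replicate 3. Clusters 4 and 6 held 1195 and 885 of the 2448 acinar-like nuclei of 7-day replicate 2, and 413 and 689 of the 1390 of 28-day replicate 3. Cluster 3 held 1506 of the 2699 acinar-like nuclei of control replicate 2 and 806 of the 1931 of 28-day replicate 2. Cluster 1 held 711 of the 1949 of control replicate 1 and 978 of the 2220 of 28-day replicate 1, while clusters 7 and 12 held 429 and 400 of the 2981 of control replicate 3. Cluster 18, led by the cell cycle genes Top2a, Mki67 and Cenpf, held 108 nuclei, of which 66 came from 7-day replicate 1. It held 12 and 6 in 7-day replicates 2 and 3, and 1, 12 and 4 in controls.

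At 7 days, acinar-like nuclei expressed more Gm5771, a predicted member of the trypsinogen family, and more Kirrel3, a cell adhesion gene, than in controls. Gm5771 stood at 57.7, 46.5 and 193 CPM (counts scaled to the library total) in the 7-day libraries against 1.20, 0.17 and 0.793 in controls (log2 fold change 7.25 ± 0.80, SE, n = 3 per group, edgeR adjusted p = 0.0494). Kirrel3 averaged 168 ± 17.6 CPM at 7 days and 3.88 ± 2.49 in controls (SD), a log2 fold change of 5.50 ± 0.65 with an adjusted p of 0.0494. Both genes lie outside the rule for naming genes and were chosen after their values were seen. Kirrel3 averaged 8.16 times more CPM in another named class than in acinar-like nuclei and was among the genes leading acinar cluster 20. Gm5771 shares sequence with other trypsinogens, so its level is uncertain. These 2 genes were the only ones of 12568 to pass by edgeR, whereas DESeq2 called 125 genes higher and 46 lower. At an unadjusted p under 0.05, edgeR gave 1406 genes (11.2%), and 2067 genes (16.4%) had no overlap between the groups, where chance gives 10%. The count fell to 0 without control replicate 1, 2 or 3, without 7-day replicate 1 or without 28-day replicate 2. It was 1 without 28-day replicate 3, 3 without 7-day replicate 2, 4 without 28-day replicate 1 and 5 without both libraries of 4 runs.

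Gene groups fixed in advance moved in acinar-like nuclei at 7 days by camera with a preset correlation. Proliferation genes were higher: 31 of 32 measured members lay above controls, none passed over all genes tested and 16 passed adjusted over the list alone (adjusted p = 7.51e-17; adjusted p = 0.279 with an estimated correlation). Mki67, a marker of cycling cells, averaged 19.5 ± 15.9 CPM at 7 days and 3.34 ± 0.775 in controls (SD), and Top2a, a topoisomerase of dividing cells, averaged 20.7 ± 11.5 and 6.32 ± 0.468. Log2 fold changes were 2.53 ± 0.70 for Mki67 and 3.19 ± 0.54 (SE) for Cenpf, a centromere protein. The list of Reg family and acute injury genes was higher, with 8 of 8 measured members above controls, 0 passing over all genes tested and 1 adjusted over the list alone (adjusted p = 2.39e-05; adjusted p = 0.279 with an estimated correlation). Without Reg2, which lacks entries in 1 library, 7 of 7 were higher (adjusted p = 2.4e-05). The member that passed over the list alone, Reg3g, a secreted lectin induced in injured pancreas, averaged 16.4 ± 14.99 CPM against 0.598 ± 0.591. Unfolded protein response genes were higher in 23 of 26 members, with 0 passing over all genes tested and 6 adjusted over the list alone (adjusted p = 7.91e-08; adjusted p = 0.279 with an estimated correlation). Among these, the chaperone Hspa5 averaged 104 ± 29.0 CPM against 57.9 ± 12.5, and Hyou1, another chaperone of the endoplasmic reticulum, 65.0 ± 19.7 against 32.7 ± 5.39.

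Interferon response and antigen presentation genes were also higher in acinar-like nuclei at 7 days, in 18 of 19 members, with 0 passing over all genes tested and 6 adjusted over the list alone (adjusted p = 7.91e-08; adjusted p = 0.279 with an estimated correlation). Ifih1, a sensor of double-stranded RNA, averaged 8.22 ± 2.05 CPM against 3.55 ± 1.15 in controls, and Rnf213 19.5 ± 12.5 against 7.70 ± 1.78. The list of p53 targets and senescence genes was higher in 9 of 10 members, with 0 over all genes tested and 1, Cdkn1a, adjusted over the list alone (adjusted p = 0.000266; adjusted p = 0.279 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, averaged 2.01 ± 0.946 CPM against 0.531 ± 0.0814. Cytoplasmic ribosomal protein genes were higher in 33 of 33 members, with 0 over all genes tested (adjusted p = 1.49e-06; adjusted p = 0.512 with an estimated correlation), a call lost without 7-day replicate 3 (0.0561). Without Rpl32 and Rplp0, which lack entries, 31 of 31 were higher (adjusted p = 7.28e-07). Circadian clock genes were lower in 11 of 14 members, with 0 over all genes tested and 3 adjusted over the list alone (adjusted p = 0.00312; adjusted p = 0.279 with an estimated correlation). Those 3 went both ways: Bhlhe41, a clock repressor, averaged 1.68 ± 1.33 CPM against 6.44 ± 1.03, while Arntl, a clock activator, had a log2 fold change of 4.94 ± 1.31 and Nfil3 of 2.55 ± 0.54. Arntl stood at 2.58, 40.8 and 0.873 CPM in the 7-day libraries, so its mean rests on replicate 2.

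Signs of RNA quality moved with the same group. All 10 mitochondrial genes tested that have entries in every library, which leaves out mt-Atp6, mt-Co3 and mt-Nd3, were higher in acinar-like nuclei of each 7-day library than of any control, with log2 fold changes from 2.04 to 2.76, and 0 of them passed by edgeR (lowest adjusted p = 0.1903). As a percentage of the TMM-scaled library size, their sum was 0.182%, 0.123% and 0.412% at 7 days and 0.0731%, 0.0222% and 0.0238% in controls. At 28 days it was 0.0218%, 0.0317% and 0.0161%. TMM factors were 0.764, 0.826 and 0.742 at 7 days and 1.083, 1.333 and 0.914 in controls. The gap between these groups is therefore smaller in plain shares of counts. The median share of counts from rRNA-like genes per acinar-like nucleus was 76.2%, 71.8% and 68.8% at 7 days, 54.1%, 46.7% and 70.0% in controls, and 59.9%, 51.7% and 54.8% at 28 days.

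The remaining acinar lists did not pass at 7 days. Digestive enzymes and zymogens lay higher in 22 of 35 members (adjusted p = 0.0644), with Cela3a, Prss3 and Prss1 passing adjusted over the list alone and 0 over all genes tested. Cela3a, an elastase family gene, averaged 171 ± 21.1 CPM against 50.2 ± 19.9, whereas the lipase Pnlip averaged 4547 ± 2913 against 6628 ± 4545. Prss1 and Prss3 are trypsinogens whose reads may be split with near-identical copies. The adjusted p was 0.5485 for acinar transcription factors, 0.1018 for ductal and metaplasia genes, 0.9677 for inflammation and NF-kB targets, 0.253 for immediate early genes, 0.3147 for MAPK feedback and EGFR ligands, 0.0621 for cholesterol synthesis and 0.0793 for glucocorticoid response. The acinar transcription factor Nr5a2 averaged 281 ± 10.96 CPM at 7 days and 344 ± 50.5 in controls, and Rbpjl 596 ± 126 and 486 ± 96.8. Cd44, a surface receptor of the metaplasia list, averaged 427 ± 209 CPM against 107 ± 48.4 (log2 fold change 2.00 ± 0.64, adjusted p = 0.3285). Phlda1, of the MAPK list, passed adjusted over the list alone with a log2 fold change of 1.91 ± 0.52 and did not pass over all genes tested. The enzyme list passed without control replicate 1 (4.04e-06), 7-day replicate 1 (0.00072) or 2 (0.0491), or 28-day replicate 2 (0.0377), and the metaplasia list without control replicate 1 (0.00577) or 3 (0.0429) or 7-day replicate 1 (0.045). Cholesterol synthesis passed without control replicate 1 (0.00304), 7-day replicate 2 (0.0327), 28-day replicate 2 (0.0424) or both libraries of 4 runs (0.0296), immediate early genes without control replicate 1 (0.0202), and glucocorticoid response without control replicate 3 (0.0424) or 7-day replicate 3 (0.002).

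**Figure D2:**
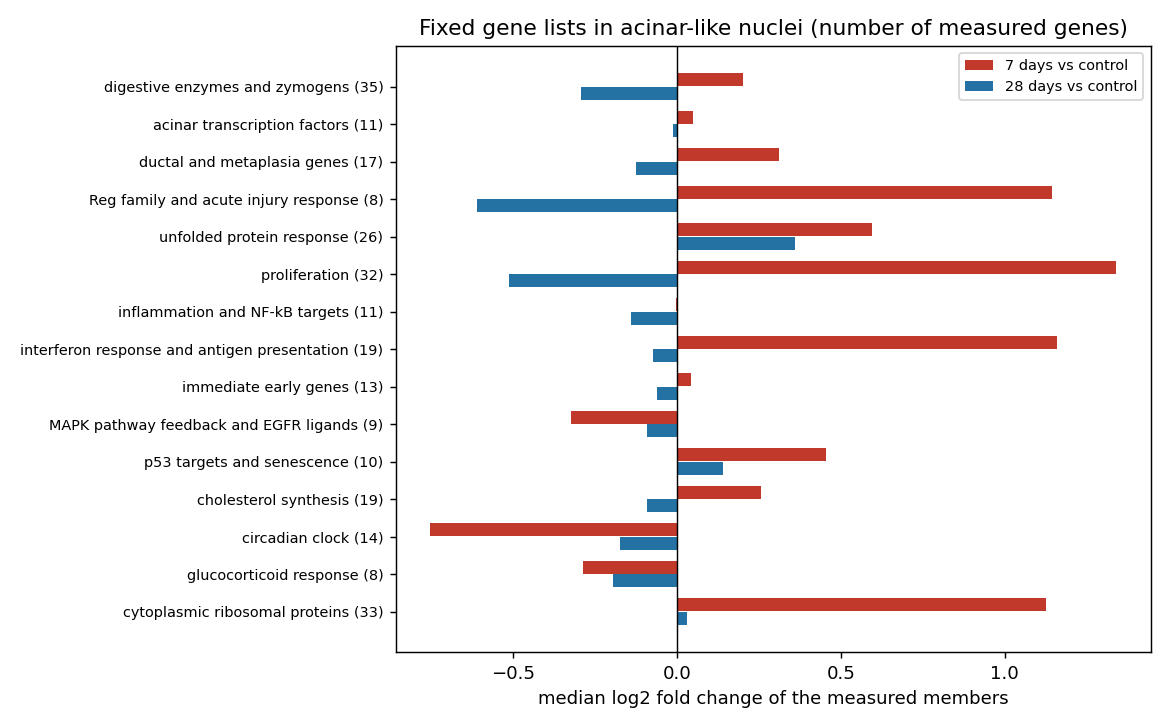
Median log2 fold change over the measured members of each fixed gene list in acinar-like nuclei, with a bar for 7 days and a bar for 28 days against controls (n = 3 libraries per group) and the number of measured genes in brackets. At 7 days the median was 1.34 for proliferation genes and -0.75 for circadian clock genes.

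At 28 days, 2 of the 15 lists passed against controls in acinar-like nuclei. Unfolded protein response genes were higher in 22 of 26 members, with 0 over all genes tested and 0 adjusted over the list alone (adjusted p = 3.15e-05; adjusted p = 0.973 with an estimated correlation). Hyou1 averaged 53.6 ± 12.5 CPM against 32.7 ± 5.39 in controls (log2 fold change 0.71 ± 0.25), and Hspa5 81.3 ± 13.8 against 57.9 ± 12.5 (0.49 ± 0.24). Proliferation genes were lower in 28 of 32 members, with 0 over all genes tested (adjusted p = 0.000156; adjusted p = 0.973 with an estimated correlation). Mki67 averaged 2.09 ± 1.40 CPM against 3.34 ± 0.775, and Top2a 4.40 ± 1.92 against 6.32 ± 0.468. The unfolded protein response call was lost without 28-day replicate 3 (0.0529) and the proliferation call without 28-day replicate 2 (0.294).

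No gene passed by edgeR in acinar-like nuclei at 28 days against controls. At an unadjusted p under 0.05 edgeR gave 939 genes (7.5%), DESeq2 called 39 genes, and 1894 genes (15.1%) had no overlap between the groups, where chance gives 10%. The other 13 lists had adjusted p values from 0.5445 to 0.9365, and the Reg family list lay lower in 7 of 8 members. Median, mean and test differed in sign for acinar transcription factors, interferon response, cholesterol synthesis and ribosomal proteins. Without 28-day replicate 2 the ribosomal list passed as higher (adjusted p = 0.00519), and it passed as lower without control replicate 2 (0.0455), 28-day replicate 1 (6.81e-05) or 3 (0.00279), or both libraries of 4 runs (0.00671). Without control replicate 2 the lists of Reg family genes, digestive enzymes, metaplasia genes and NF-kB targets passed (adjusted p = 0.0281 each), and the enzyme list also passed without 28-day replicate 1 (1.86e-05).

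Between the treated groups, acinar-like nuclei expressed less Gm5771 and less Msrb3, a methionine sulfoxide reductase, at 28 days than at 7 days. Gm5771 stood at 1.28, 0.36 and 0.955 CPM at 28 days (log2 fold change -6.89 ± 0.77, SE, n = 3 per group, edgeR adjusted p = 0.0278). Msrb3 stood at 4.97, 1.71 and 3.30 CPM at 28 days, 68.1, 48.7 and 47.0 at 7 days and 19.2, 8.41 and 22.9 in controls (log2 fold change 28 days against 7 days -4.06 ± 0.45, adjusted p = 0.0278). Msrb3 did not pass against controls at 7 days (adjusted p = 0.241) or at 28 days (adjusted p = 0.506), and another class held 6.14 times more of it. Both genes lie outside the naming rule and were chosen after their values were seen. They were the only 2 of 12568 to pass by edgeR, against 244 by DESeq2. At an unadjusted p under 0.05, edgeR gave 1336 genes (10.6%), and 1857 (14.8%) had no overlap, where chance gives 10%. The count fell to 0 without control replicate 1 or 3, without 7-day replicate 1, without any of 28-day replicates 1, 2 or 3, and without both libraries of 4 runs. It was 3 without control replicate 2, 10 without 7-day replicate 2 and 5 without 7-day replicate 3.

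Between 7 and 28 days, 8 of the 15 lists passed in acinar-like nuclei. Proliferation genes were lower at 28 days in 31 of 32 members, with 0 over all genes tested and 24 adjusted over the list alone (adjusted p = 2.93e-31; adjusted p = 0.26 with an estimated correlation). The Reg family list was lower in 8 of 8 members, with Reg3b and Reg3g passing adjusted over the list alone and 0 over all genes tested (adjusted p = 3.52e-06; adjusted p = 0.26 with an estimated correlation). Without Reg2, 7 of 7 were lower (adjusted p = 1.18e-05). Interferon response genes were lower in 17 of 19 members, with 0 over all genes tested and 5 adjusted over the list alone (adjusted p = 2.42e-07; adjusted p = 0.26 with an estimated correlation). Ribosomal protein genes were lower in 32 of 33 members, with 0 over all genes tested (adjusted p = 9.04e-09; adjusted p = 0.503 with an estimated correlation), and 30 of 31 without Rpl32 and Rplp0 (adjusted p = 1.87e-08). The p53 list was lower in 9 of 10 members, with 0 over all genes tested and Ccng1 and Cdkn1a adjusted over the list alone (adjusted p = 0.00448; adjusted p = 0.26 with an estimated correlation). Without 7-day replicate 3 the p53 call was lost (0.0529).

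Digestive enzyme genes were lower at 28 days than at 7 days in 25 of 35 members, with 0 over all genes tested and Cela3a, Prss3 and Prss1 adjusted over the list alone (adjusted p = 0.00448; adjusted p = 0.581 with an estimated correlation), and 24 of 34 were lower without Klk1 (adjusted p = 0.00545). Ductal and metaplasia genes were lower in 13 of 17 members, with 0 over all genes tested (adjusted p = 0.019; adjusted p = 0.557 with an estimated correlation), and Krt18, a keratin of this list, had a log2 fold change of -1.44 ± 0.43. Circadian genes were higher in 11 of 14 members, with 0 over all genes tested (adjusted p = 0.0111; adjusted p = 0.477 with an estimated correlation). The enzyme call was lost without 7-day replicate 3 (0.4516), 28-day replicate 2 (0.344), 28-day replicate 3 (0.0611) or both libraries of 4 runs (0.0507). The metaplasia call was lost without 7-day replicate 3 (0.0957), 28-day replicate 2 (0.0949), 28-day replicate 3 (0.1083) or both libraries of 4 runs (0.1531). The circadian call was lost without 7-day replicate 2 (0.3384), 28-day replicate 1 (0.0666) or both libraries of 4 runs (0.2514). The remaining lists had adjusted p values of 0.718 for acinar transcription factors, 0.1689 for the unfolded protein response, 0.1959 for NF-kB targets, 0.0964 for immediate early genes, 0.7557 for the MAPK list, 0.0689 for cholesterol synthesis and 0.382 for glucocorticoid response. Of these, the unfolded protein response passed without 7-day replicate 2 (0.00108), 28-day replicate 3 (0.00255) or both (1.32e-07), cholesterol synthesis without 7-day replicate 2 (0.0388), 28-day replicate 3 (0.00252) or both (0.00117), immediate early genes without 7-day replicate 2 (0.0198) or both (0.0178), and glucocorticoid response without 7-day replicate 3 (0.0265).

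Changes at 7 and 28 days share the same 3 controls, so their likeness was set against simulated unchanged groups. Fold changes had a covariance of 0.1046 across genes, beside 0.1136 in the simulated groups (0.1015 to 0.1269 over 50 draws). Their correlation across genes, which are not independent replicates, was 0.3163, below the simulated range of 0.4636 to 0.5361. The same sign was found in 64.8% of genes, below the simulated 66.05% to 67.87%. Each simulated gene was drawn on its own, so these ranges leave out variation that genes share and may be too narrow. They cannot decide whether the likeness differs from what shared controls give. The covariance moved to 0.2568 without control replicate 1, 0.331 without control replicate 2, 0.1676 without control replicate 3, 0.1656 without 7-day replicate 3 and 0.0684 without 28-day replicate 3, and the simulation was not repeated for these. No gene was called by edgeR against controls at both times. DESeq2 called 7 at both, where lists with no shared controls would share 0.237. No simulated value was computed for the DESeq2 lists and the 3 controls cannot be split into parts of at least 2 libraries each, so part of that excess may come from the shared controls.

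In ductal-like nuclei at 7 days, Spon1, a secreted matrix protein gene, and Astn2, a membrane protein gene, fell. Spon1 averaged 50.9 ± 5.54 CPM against 175 ± 13.6 in controls (SD, n = 3; log2 fold change -1.77 ± 0.19, SE, edgeR adjusted p = 0.00505). Astn2 averaged 32.9 ± 6.22 CPM against 132 ± 32.4 (log2 fold change -1.97 ± 0.21, adjusted p = 0.00505). Interferon response genes were higher in 23 of 27 members, with 0 over all genes tested and 7 adjusted over the list alone (adjusted p = 1.42e-10; adjusted p = 0.364 with an estimated correlation). Ifit1, an antiviral effector, averaged 24.0 ± 15.3 CPM against 3.49 ± 3.08, and Stat2, a transducer of interferon signals, had a log2 fold change of 1.32 ± 0.42. Circadian genes were lower in 10 of 12 members, with 0 over all genes tested (adjusted p = 0.00659; adjusted p = 0.364 with an estimated correlation), and Hlf, a clock output factor, averaged 40.5 ± 17.0 CPM against 73.8 ± 6.96. The other lists did not pass: ductal and metaplasia genes (0.8631), proliferation (0.2364), NF-kB targets (0.3207) and ribosomal proteins (adjusted p = 0.0673). Cftr, a chloride channel of duct cells, passed adjusted over the metaplasia list alone and not over all genes tested, with 170 ± 57.0 CPM against 414 ± 77.5. It was among the genes leading ductal clusters 1 and 4 of the second clustering. These held 195 and 113 of the 1028 ductal-like nuclei of 7-day replicate 1, and 10 and 94 of the 194 of 7-day replicate 2. Whether the mix of the summed ductal clusters bears on Cftr, Spon1 or Astn2 was not tested.

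Spon1 and Astn2 were the only 2 of 9055 genes to pass in ductal-like nuclei at 7 days, against 40 by DESeq2 and 570 (6.3%) at an unadjusted p under 0.05 by edgeR. Both lost the call without control replicate 2 (0.0512) and without 7-day replicate 3 (0.0658). The count was 3 without control replicate 3, 4 without 7-day replicate 2 or 28-day replicate 3, and 6 without both libraries of 4 runs. The circadian call was lost without 7-day replicate 2 (0.2953) or both libraries of 4 runs (0.3147), and the ribosomal list, lower in the full comparison, passed as higher without 7-day replicate 1 (0.000295). The ribosomal list passed as lower without control replicate 2 (0.00373), 7-day replicate 2 (0.000453) or 3 (2.53e-07), 28-day replicate 1 (0.0497), 2 (0.0336) or 3 (0.0462), or both libraries of 4 runs (0.000377). The proliferation list passed without control replicate 2 (0.00373), 7-day replicate 2 (0.0248) or 3 (0.000353), or 28-day replicate 1 (0.0285) or 2 (0.0322).

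At 28 days, no gene passed by edgeR in ductal-like nuclei, and the genes that had fallen at 7 days stood between the other groups, with Spon1 at 107 ± 29.7 CPM and Astn2 at 96.0 ± 14.8. At an unadjusted p under 0.05 edgeR gave 405 genes and DESeq2 called 4. The count was 1 without 7-day replicate 2 or 28-day replicate 2, and 2 without both libraries of 4 runs. Ribosomal protein genes were lower in 26 of 33 members, with 0 over all genes tested (adjusted p = 0.0153; adjusted p = 0.87 with an estimated correlation), a call lost without control replicate 3 (0.1601) or 28-day replicate 2 (0.7695). Without Rpl32 and Rplp0, 24 of 31 were lower (adjusted p = 0.017). Interferon response genes did not differ (adjusted p = 0.933), and passed as higher without control replicate 1 (0.00274) and as lower without control replicate 2 (0.032). The other lists had adjusted p values of 0.2626 for metaplasia genes, 0.2626 for proliferation, 0.3662 for NF-kB targets and 0.933 for circadian genes, and the metaplasia list passed without control replicate 2 (0.00468) or 28-day replicate 1 (0.0012).

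Fibroblast-like nuclei at 7 days had more transcripts of matrix genes. Genes of extracellular matrix and fibrosis were higher in 25 of 27 members, with 0 over all genes tested and Postn and Adam12 adjusted over the list alone (adjusted p = 3.55e-08; adjusted p = 0.3185 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, averaged 138 ± 8.73 CPM against 29.0 ± 36.8 in controls (log2 fold change 2.09 ± 0.55), and Adam12, a metalloproteinase, 196 ± 36.6 against 62.8 ± 46.2. Circadian genes were lower in 9 of 10 members, with 0 over all genes tested (adjusted p = 7.16e-06; adjusted p = 0.3021 with an estimated correlation), and Nr1d1, a clock repressor, averaged 42.6 ± 22.8 CPM against 106 ± 45.0. Interferon response genes were higher in 15 of 19 members, with 0 over all genes tested (adjusted p = 0.0474; adjusted p = 0.4762 with an estimated correlation). In the same nuclei H2-Ab1 and Cd74, MHC class II genes of immune cells chosen after their values were seen, were higher at 7 days without passing by edgeR. H2-Ab1 stood at 32.8, 82.6 and 127 CPM against 6.12, 0 and 0 in controls (adjusted p = 0.0808), and Cd74 at 66.8, 193 and 193 against 12.2, 4.98 and 15.2 (adjusted p = 0.0813), and the highest other class held 26.4 times as much H2-Ab1 and 30.5 times as much Cd74. With stored values rounded up and entries stored as 0 counted as 1, H2-Ab1 had a log2 fold change of 5.19 and Cd74 of 3.21 and both passed (adjusted p = 0.0468 each), as both did by DESeq2 on the values as stored. Droplets with transcripts of immune cells are therefore not excluded for the interferon call. The interferon call was lost without control replicate 2 (0.1868), control replicate 3 (0.5737), 7-day replicate 1 (0.6475) or 28-day replicate 2 (0.0502). NF-kB targets (0.3783), glucocorticoid response (0.0523) and ribosomal proteins (adjusted p = 0.0523) did not pass. The ribosomal list passed without control replicate 2 (9.04e-06), 7-day replicate 2 (0.00207) or 3 (0.000387), 28-day replicate 1 (0.0487), 2 (0.038) or 3 (0.0216), or both libraries of 4 runs (0.000111), and the glucocorticoid list without 7-day replicate 3 (6.38e-06) or 28-day replicate 1 (0.0487).

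No gene passed by edgeR in fibroblast-like nuclei at 7 days (258 of 5030 at an unadjusted p under 0.05; 6 by DESeq2). The count was 3 without 7-day replicate 1 or 28-day replicate 3 and 1 without 7-day replicate 3. At 28 days ribosomal protein genes were lower in 30 of 32 members, with 0 over all genes tested (adjusted p = 3.03e-18; adjusted p = 0.3414 with an estimated correlation). Without Rpl32, which has no entry in 28-day replicates 1 and 2, 29 of 31 were lower (adjusted p = 7.22e-18). Rplp1, a protein of the large subunit, averaged 21.5 ± 37.2 CPM against 132 ± 77.8 in controls (SD). The SD also exceeded the mean at 28 days for other members, such as Rps6 (8.37 ± 14.5 CPM) and Rps14 (22.0 ± 38.1). Such members lay near 0 in some 28-day libraries, and the list was not tested again with values rounded up. The matrix list did not pass at 28 days (adjusted p = 0.2876), nor did NF-kB targets and the interferon list (0.1076 each), circadian genes (0.5172) or glucocorticoid response (0.229). No gene passed by edgeR at 28 days, against 176 at an unadjusted p under 0.05 and 0 by DESeq2. At 28 days the matrix list passed without control replicate 1 (1.25e-05), 28-day replicate 2 (0.0196) or 3 (0.0229), or both libraries of 4 runs (0.0296), NF-kB targets without control replicate 3 (0.0127), 28-day replicate 3 (0.0207) or both libraries of 4 runs (0.0229), and the interferon list without control replicate 3 (0.000293).

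In macrophage-like nuclei, ribosomal protein genes were lower at both times. At 7 days 12 of 14 members were lower, with 0 over all genes tested (adjusted p = 0.000523; adjusted p = 0.9206 with an estimated correlation), and at 28 days 14 of 14 (adjusted p = 1.31e-08; adjusted p = 0.4456 with an estimated correlation). Rplp1 averaged 21.3 ± 21.9 CPM at 28 days and 205 ± 57.8 in controls (SD). Interferon response genes were lower at 28 days in 8 of 9 members, with 0 over all genes tested (adjusted p = 0.0259, or adjusted p = 0.5154 with an estimated correlation). B2m, the light chain of class I antigen presentation, averaged 292 ± 163 CPM against 463 ± 162 (SD), and the groups overlapped. All 6 MHC class II genes lay lower at both times without passing (adjusted p = 0.1723 at 7 days and 0.0596 at 28 days). NF-kB targets, interferon response and the list of macrophage activation and lipid handling each had an adjusted p of 0.8552 at 7 days, and at 28 days NF-kB targets had 0.3289 and the activation list 0.344.

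No gene passed by edgeR or DESeq2 in macrophage-like nuclei at 7 or 28 days, with 64 and 75 of 1939 genes at an unadjusted p under 0.05 by edgeR. Without control replicate 2 the count was 2 at 7 days and 1 at 28 days. The ribosomal call at 7 days was lost without control replicate 1 (0.1836) and turned to higher without passing when 7-day replicate 1 was left out (0.1773). The MHC class II list passed at 7 days without control replicate 3 (0.0219) or 28-day replicate 1 (0.0133), and at 28 days without control replicate 2 (0.048) or 3 (0.00411), 7-day replicate 2 (0.0407) or 28-day replicate 1 (2.02e-12). The interferon list passed at 7 days without both libraries of 4 runs (0.0111). The interferon call at 28 days was lost without control replicate 1 (0.2837), control replicate 2 (0.0816), 7-day replicate 1 (0.0643), 28-day replicate 2 (0.4206), 28-day replicate 3 (0.1401) or both libraries of 4 runs (0.3221).

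In endothelial-like nuclei, glucocorticoid response genes were lower at 7 days in 5 of 6 members, with 0 over all genes tested (adjusted p = 0.00736; adjusted p = 0.7552 with an estimated correlation). Tsc22d3, a glucocorticoid-induced leucine zipper gene, averaged 63.5 ± 48.4 CPM against 105 ± 12.1, and Zbtb16, a zinc finger transcription factor gene, 207 ± 202 against 326 ± 77.8. That call was lost without control replicate 1 (0.1606), 2 (0.1464) or 3 (0.2509), without 7-day replicate 1 (0.3154) or 2 (0.7925), without 28-day replicate 1 (0.1095) or 2 (0.1862), and without both libraries of 4 runs (0.1673). Ribosomal protein genes were lower at 28 days in 28 of 33 members, with 0 over all genes tested (adjusted p = 0.0194; adjusted p = 0.8369 with an estimated correlation), and 26 of 31 without Rpl32 and Rplp0 (adjusted p = 0.0321). That call was lost without 28-day replicate 2 (0.8899) or 3 (0.1039) and changed sign without control replicate 1 (0.9912). At 7 days the same list passed as higher without 7-day replicate 1 (2.25e-06) and as lower without 7-day replicate 2 (0.000108), 7-day replicate 3 (0.0119) or both libraries of 4 runs (6.17e-05). The other lists did not pass at 7 days: NF-kB targets (0.9197), interferon response (0.3775), immediate early genes (0.6037), angiogenesis (0.9197), circadian genes (0.1907) and ribosomal proteins (adjusted p = 0.5542). At 28 days adjusted p values were 0.7019 for NF-kB targets, circadian genes and glucocorticoid response, 0.6355 for interferon response, and 0.5195 for immediate early genes and angiogenesis. The interferon list passed without control replicate 1 at 7 days (0.0218) and at 28 days (0.0418), the circadian list at 7 days without 7-day replicate 3 (0.0046), and the angiogenesis list at 28 days without 28-day replicate 1 (0.0399). No gene passed by edgeR or DESeq2 at either time, with 134 and 151 of 4957 genes at an unadjusted p under 0.05 by edgeR, and 2 passed at 28 days without both libraries of 4 runs.

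In beta-like nuclei, the insulin-producing cells, Ins1 did not pass and averaged 64470 CPM at 7 days, 71560 at 28 days and 72170 in controls. This class was small, with 11 nuclei in 7-day replicate 2 and 16 in 28-day replicate 3. Unfolded protein response genes were higher at 28 days in 11 of 14 members, with 0 over all genes tested (adjusted p = 0.0331, or adjusted p = 0.3123 with an estimated correlation). Calr, a calcium-binding chaperone, averaged 118 ± 80.7 CPM against 84.4 ± 66.5 (SD), and the groups overlapped. By the fitted log2 fold change, ribosomal protein genes were lower at 28 days in 5 of 5 members, with 0 over all genes tested (adjusted p = 0.0224, or adjusted p = 0.1203 with an estimated correlation). The mean of Rpl4 was nevertheless higher, at 14.5 ± 25.1 CPM against 10.8 ± 18.8 in controls (SD). Its log2 fold change was -0.27 ± 1.44 (SE), so its direction is uncertain. The unfolded protein response call was lost without control replicate 2 (0.3957) or 3 (0.6984), 7-day replicate 1 (0.0506), 28-day replicate 1 (0.1382) or 3 (0.2302), or both libraries of 4 runs (0.2272). The ribosomal call was lost without control replicate 1 (0.0807), 2 (0.141) or 3 (0.6984), 7-day replicate 1 (0.0506), or 28-day replicate 1 (0.2845) or 2 (0.5689). Lists that did not pass were the unfolded protein response (0.1622), beta cell function (0.8206), circadian genes (0.8956) and ribosomal proteins (adjusted p = 0.1094) at 7 days, and beta cell function and circadian genes (adjusted p = 0.4914 each) at 28 days. At 7 days the unfolded protein response passed without control replicate 1 (0.00538), and the ribosomal list without 7-day replicate 2 (0.000126) or both libraries of 4 runs (0.0022). The only gene called by edgeR in beta-like nuclei at either time, Pde1c, has no entry in control replicates 1 and 3, and its entries in control replicate 2 are listed at 0, so it is not reported as a change. Without the genes that lack entries the count was 0 at both times, and 133 genes at 7 days and 116 at 28 days had an unadjusted p under 0.05 by edgeR.

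**Figure D3:**
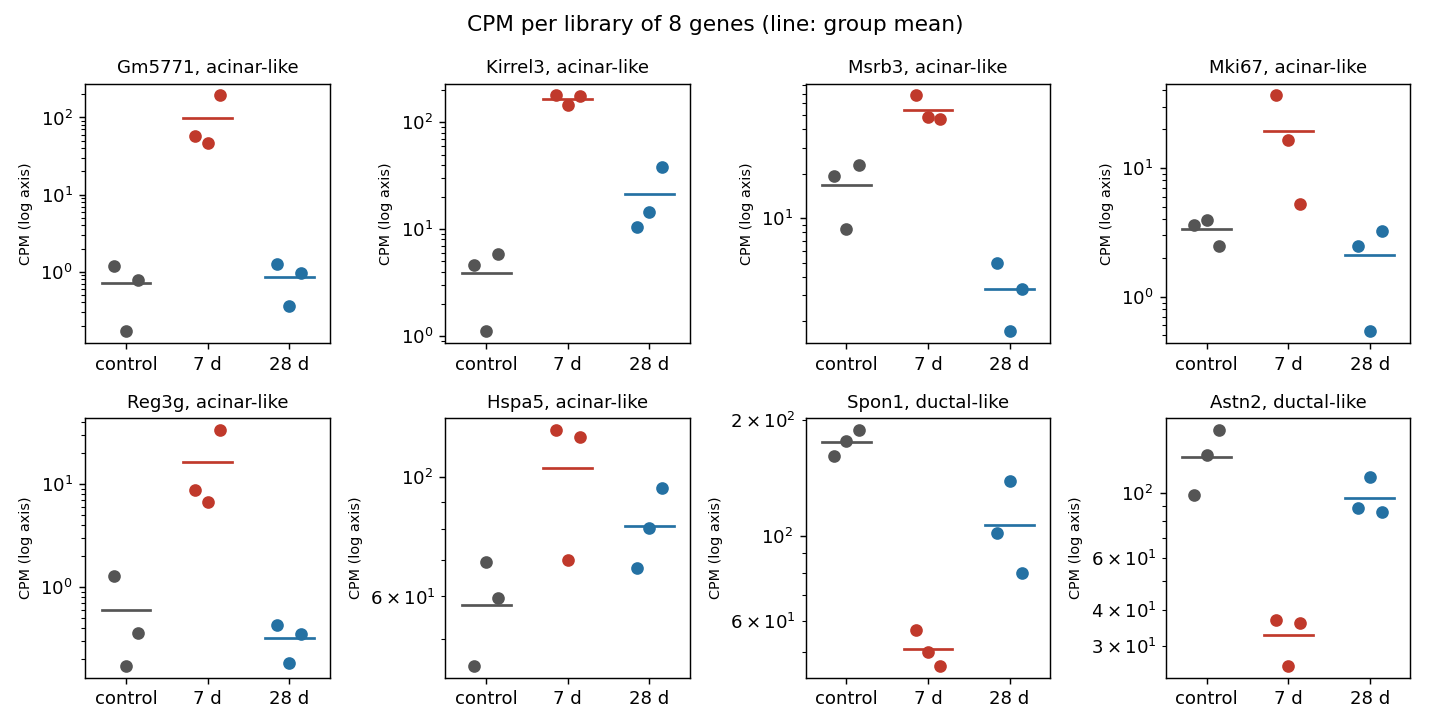
CPM in each library (log axis), one point per mouse (n = 3 per group), for 6 genes in acinar-like and 2 in ductal-like nuclei, with lines at the group means. In acinar-like nuclei Gm5771 lies at 46.5 or above in the 7-day libraries and at 1.28 or below in the others.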

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

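The tests weighed for Gm5771 and for the circadian genes, and the proliferation test without 7-day replicate 1, were chosen after the result was seen; the proliferation tests on doublets and depth were written before. Acinar-like nuclei at 28 days and at 7 days differed by the test of that difference itself in 2 genes and 8 gene lists. Gm5771 had a log2 fold change of -6.89 at 28 days against 7 days, and Msrb3 of -4.06. The adjusted p of that difference was 2.93e-31 for proliferation, 9.04e-09 for cytoplasmic ribosomal proteins, 2.42e-07 for interferon response and 3.52e-06 for the Reg family. It was 0.00448 for digestive enzymes, 0.00448 for p53 targets, 0.0111 for the circadian clock and 0.019 for ductal and metaplasia genes. None of these 8 list calls passed with an estimated correlation.

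Gm5771, near absent in controls and at 28 days, was higher in acinar-like nuclei of every 7-day library, by 7.25 ± 0.80 on the log2 scale. Reads of the abundant trypsinogens Prss2, Try4 and Try5 would have carried it along only if these rose alike, and their median log2 fold change was 0.334. With stored values rounded up and entries stored as 0 counted as 1, the log2 fold change was 5.31 ± 0.73. The edgeR adjusted p went to 0.122 as the fold shrank. Whether counts were deducted before deposit is not given in the sources used here. A deduction of up to 1 count per entry would not account for most of the difference, and a larger one was not tested. Reads shared among scarce trypsinogen genes stay open: Prss1, Prss3, Gm2663 and Gm10334 had log2 fold changes of at least 3.96, and a rise of the whole family or a sharing of reads cannot be told apart. No test of a biological explanation was run, and cage and age are confounded with the group.

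Proliferation genes stood higher in acinar-like nuclei at 7 days, with a median log2 fold change of 1.34. The median was 1.37 without the 5% highest doublet scores. This does not decide on doublets, because the same scoring called only 36 nuclei and may not find them. With each nucleus thinned to 1000 counts the median was 1.23. Thinning keeps the expected proportions within a nucleus, so it cannot decide whether depth mattered. Without 7-day replicate 1, which held most of the cycling cluster, the median was 0.87. That library alone thus does not account for the higher list. The cycling cluster itself held 66, 12 and 6 nuclei in the 7-day libraries and 1, 12 and 4 in controls. Outside 7-day replicate 1 its numbers of nuclei overlapped with those of controls. No test of a biological explanation was run. Doublets, depth per nucleus, RNA quality, which moved with the group, and cage stay open.

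Circadian clock genes were lower at 7 days in acinar-like, ductal-like and fibroblast-like nuclei. Without 7-day replicate 2 the adjusted p was 0.0477 in acinar-like nuclei, close to the threshold, 0.00977 in fibroblast-like nuclei and 0.2953 in ductal-like nuclei, so that library may carry the ductal call and not the fibroblast one. By the sign of camera the list was lower in 5 of 5 classes tested, but it passed in 3 of them: 6 of 10 members were lower in endothelial-like nuclei (adjusted p = 0.1907), and in beta-like nuclei 4 of 6 were higher, with a positive median and mean (adjusted p = 0.8956). The hour of the day at which the mice were killed is not in the labels, so an effect of the hour and an effect of cerulein on the clock cannot be told apart.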

How the results depend on the processing

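The added alternatives, all chosen after the data were seen, were leaving out both libraries of 4 runs, leaving out the 5% highest doublet scores, rounding up, leaving out genes with missing values or rRNA-like genes, and markers against all other nuclei. The minimum of 1000 counts removed no nucleus and gave no value. The cause of each move was not tested. How far depth limits the calls was not tested on simulated data.

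Counts of changed genes moved most with the tool in acinar-like nuclei and with the filter in the other classes. DESeq2 gave 171 acinar genes at 7 days, 39 at 28 days and 244 between the treated groups, 40 and 4 ductal genes at 7 and 28 days, and 6 fibroblast genes at 7 days. Without a filter edgeR called 18 and 56 acinar genes (7 days, 28 against 7 days), 112 and 48 ductal, 60 and 59 fibroblast, 8 and 26 macrophage, 43 and 54 endothelial, and 14 and 12 beta genes (7 and 28 days). Without both libraries of 4 runs, acinar counts were 5 at 7 days and 0 between the treated groups, ductal 6 and 2, endothelial 2 at 28 days and beta 2 at 7 days. With values rounded up, acinar counts were 0 and 1, ductal 3 and 1, fibroblast 4 at 7 days, and beta 0 at both times; beta was also 0 without missing genes. Without the 5% highest doublet scores the acinar counts were 0 at 7 days and 6 between the treated groups, with nuclei thinned 7 and 13, with run number as covariate 4 and 7, and with only the 2 groups compared 0 and 0. At Leiden 2 the acinar count at 7 days was 0. Between the treated groups it was 7 without scrublet removal and 4 over all nuclei. With markers against all other nuclei the ductal count at 7 days was 6.

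Leaving out each library, counts ran from 0 to 4 for acinar at 7 days, 0 to 10 between the treated groups, 0 to 4 for ductal at 7 days and 0 to 1 at 28 days, 0 to 3 for fibroblast at 7 days, 0 to 2 for macrophage at 7 days and 0 to 1 at 28 days, and 0 to 2 for beta at both times. Gm5771 lost its call at 7 days without control replicate 1 (0.179), 2 (0.119) or 3 (0.228), 7-day replicate 1 (0.0955) or 28-day replicate 2 (0.0833) or 3 (0.0619), at Leiden 2 (0.0588), without the 5% highest doublet scores (0.0553) and with only the 2 groups compared (0.0781).

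Share changes are log2 fold changes against controls, none past the threshold. TMM over classes gave 0.15 for acinar at 7 days (first reported -0.028) and -0.027 for ductal at 28 days. Without scrublet removal, for which clustering and naming were redone, macrophage shares gave -0.056 at 7 days and -0.079 at 28 days. Endothelial shares at 28 days gave 0.18 at Leiden 2, 0.003 without the highest doublet scores and 0.081 without both libraries of 4 runs, and T or NK shares gave 0.15 at 7 days without both libraries. Leaving out each library gave -0.14 to 0.047 for acinar, -0.059 to 0.62 for ductal, -0.47 to 0.89 for beta and -0.52 to 0.25 for T or NK at 7 days, and -0.071 to 0.033 for acinar, -0.12 to 0.29 for ductal, -0.19 to 0.093 for endothelial and -0.66 to 0.11 for T or NK at 28 days.

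List calls numbered 31 of 101, 0 with an estimated correlation, 0 by fry and 29 to 39 leaving out each library; 31 held without missing genes and 24 without both libraries of 4 runs. Over all list values, 1107 kept direction and side, 114 lost the call, 86 gained it, 101 moved without a call and 6 turned. The 6, with the range of adjusted p leaving out each library, were ribosomal proteins in acinar-like nuclei at 28 days (0.00519; 6.81e-05 to 0.4933), in ductal-like nuclei at 7 days (0.000295; 2.53e-07 at the lowest), in macrophage-like nuclei at 7 days (0.1773; 2.64e-08 at the lowest) and in endothelial-like nuclei at 7 days (2.25e-06; 0.4819 at the highest) and 28 days (0.9912; 1.05e-06 at the lowest), and interferon response in ductal-like nuclei at 28 days (0.00274; 0.9459 at the highest). DESeq2 shared 7 genes between 7 and 28 days in place of 0.

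With the replicate number as a block the ductal count at 7 days was 3. Whether replicate numbers mark shared handling cannot be told. In acinar-like nuclei, deviations from the group mean correlated between -0.169 and 0.245 for same-numbered libraries, and between -0.313 and 0.303 for differently numbered ones. The highest value, 0.303, was that of 7-day replicate 2 with 28-day replicate 3, the 2 libraries of 4 runs. Whether the runs account for it was not tested. By chi-square over degrees of freedom, the closest pairs of libraries were same-numbered. They were control and 28-day replicates 1 (24.21) and control and 28-day replicates 2 (38.14). The block changed no list call among the 31 and brought 5 others past the threshold, MHC class II in macrophages (0.0105) among them.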

Other observations

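All tests of other splits, and the genes named here, were chosen after the result was seen. Macrophage-like nuclei held more Ms4a7 and less Timd4 in the treated groups, without passing by edgeR. Ms4a7, a gene of tissue macrophages, averaged 85.6 ± 43.3 CPM in controls, 320 ± 109 at 7 days and 220 ± 50.0 at 28 days (SD, n = 3; log2 fold change at 7 days 1.77 ± 0.37, SE, adjusted p = 0.7102). Timd4, a phosphatidylserine receptor of resident macrophages, averaged 147 ± 15.2 CPM in controls, 60.5 at 7 days and 31.6 at 28 days (log2 fold change at 28 days -2.47 ± 0.60).

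In acinar-like nuclei, Kirrel3 stood between the groups at 28 days, at 21.2 ± 15.2 CPM, beside 168 ± 17.6 at 7 days and 3.88 ± 2.49 in controls. The first principal component of acinar-like libraries held 24.2% of the variance with scores from -59.2 in 7-day replicate 3 to 53 in 28-day replicate 2.

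Each contrast of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. Real and highest other counts of changed genes were 2 and 0 for acinar at 7 days (1 split as large), 0 and 1 for acinar at 28 days (10 splits), 2 and 1 between the treated groups (1 split), and 2 and 0 for ductal at 7 days (1 split). They were 0 and 5 for ductal at 28 days, 0 and 0 for fibroblast at 7 days and 0 and 1 at 28 days, 0 and 6 for macrophage at 7 days and 0 and 0 at 28 days, and 0 and 1 for endothelial at both times (10 splits each). For beta they were 1 and 2 at 7 days (5 splits) and 1 and 1 at 28 days (4 splits). The ductal split of 5 set control replicates 1 and 3 with 28-day replicate 1, and the macrophage split of 6 set control replicates 1 and 2 with 7-day replicate 3, which may point to a structure of the samples other than the groups and was not tested further.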
